A study of Ovis aries with 8 samples.

How the data were processed

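Liver pieces of 8 lambs were kept in RNAlater and homogenised, and total RNA was purified with DNase treatment, per the labels' protocols. Poly(A) RNA was made into indexed libraries, and their pool was sequenced as paired reads of 100 bases on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4 and DESeq2 1.12.4. The aligner, the read counter and the genome build are not given in the sources used here, so it is open how reads that match several genes were counted and whether counting used strand. Poly(A) selection keeps mature messenger RNA and captures other RNAs only in part.

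The authors deposited 1 table of 27729 genes that holds, for each lamb, TPM values made from gene counts and a gene length, per the file headers. The columns all sum to the same total, so a TPM value is a share: a few abundant genes that take less of it raise all others. The same table holds the authors' DESeq2 result, per the file headers: the mean of normalized counts, a coverage-like signal scaled by the authors with size factors, the log2 fold change (shrunken and unshrunken) with its standard error, the Wald statistic, a score deposited beside it, and the deposited p-value and adjusted p-value. The deposited direction was checked against the TPM means and is RES over ADL. The log2 fold changes quoted from that table are the shrunken ones. The annotation columns give chromosome, start and end; their counting base is not stated.

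The TPM values, multiplied by the deposited gene length and divided by the smallest value above 0 in each library, came out as whole numbers for 100% of the values within a tolerance of 1e-06. These recovered reads, divided by median-of-ratios size factors, gave the deposited mean of normalized counts with a ratio of 1 for every gene with one. The depth is therefore known: 14618968, 15006674, 16182407 and 15905894 assigned reads in ADL lambs 1 to 4, and 14514084, 15287690, 15410295 and 14749371 in RES lambs 1 to 4. The number of reads behind a TPM value depends on the length of the gene, and a gene with fewer reads holds more counting noise in its spread.

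Groups were taken from the sample titles, and table columns from the titles in the table's header. The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Values were transformed to log2(TPM + 1), genes with a mean of at least 1 TPM over the 8 lambs were kept (13437), and RES was compared with ADL by limma 3.58.1 (lmFit, and eBayes with a trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are RES minus ADL on that log2 scale, with limma's moderated standard error. The authors' test was not run again; its results are quoted.

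Lists of genes were tested with camera (limma, two-sided) at its preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. Of the 45 lists, 42 had at least 5 measured members. Of their 1215 symbols, 1081 were found in the table, 41 of them through the current symbol of the same Entrez identifier in a sheep RefSeq gene table and 20 through an alias in the file; 21951 identifiers of the file were in that RefSeq table. Members were also adjusted over their list alone. A score per lamb, the mean log2(TPM + 1) over a list's members, was tested by exact two-sided permutation over 70 assignments for the lists of cell types and those past the camera threshold.

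Named genes are the 10 per direction with the largest difference past the limma threshold, or where fewer pass, those with the smallest unadjusted p, said to be short of it; up to 10 per direction by the authors' adjusted p under 0.05; and from each list described, up to 4 members past the threshold over the list alone, otherwise the 2 with the smallest p. Symbols starting with LOC were treated as symbols where the file gives a description. Genes named outside this rule were chosen after their values were seen and are described as such.

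The scripts were tested on simulated data in which 200 of the genes per simulation were changed between groups of 4, with the spread of these lambs. In the RES against ADL design, limma called 1.6% of genes changed 1.3-fold, 17.6% of those changed 1.5-fold, 64.4% of those changed 2-fold and 84.4% of those changed 3-fold, and 0.0608% of unchanged genes. A shift of -0.2 log2 units in the ribosomal protein list was called in 5 of 5 simulations, and 2 of 202 other lists were. In these simulations genes varied independently of one another.

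Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter on low values, a minimum mean of 5 TPM, TPM over size factors, quantile normalization, robust eBayes, array weights, each lamb left out, the lamb number as a block, an adjusted p under 0.1 and, for lists, an estimated correlation and fry. Alternatives chosen after seeing the data were limma's voom on the recovered reads, adjustment over the genes that have a deposited adjusted p, removal of each lamb's trend on gene length, and adjustment of the deposited p over genes with a mean of at least 1 TPM. No column of the table was left out.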

Results

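Gene expression was measured in the liver of 8 lambs by sequencing of poly(A)-selected RNA. There were 4 lambs in the group labelled ADL and 4 in the group labelled RES. The labels do not spell the 2 names out. The title of the series places the work on lambs whose feed was restricted while they were suckling and which were then fattened. All 8 lambs carried the same slaughter weight, 27 kg, in their labels. The labels number the lambs 1 to 4 within each group, and each library is from a separate lamb, so the spread between libraries is that between animals. Between 14514084 and 16182407 reads per lamb were assigned to genes. In each lamb 19117 to 19435 genes lay above 0 TPM, a share of transcripts scaled to the same total in each library. Of the 27729 genes in the table, 13437 had a mean of at least 1 TPM over the 8 lambs and were tested. Albumin, the main plasma protein made by hepatocytes, took 9.43 to 14.8% of all TPM in a lamb, and the mitochondrially encoded genes took 5.27 to 8.32%.

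The 8 livers resembled one another about as much across the groups as within them. Pearson's correlation of log2(TPM + 1), computed across genes, lay between 0.969 and 0.985 for the 12 pairs of lambs of one group. It lay between 0.967 and 0.983 for the 16 pairs of lambs from different groups. The first 2 principal components of the 500 most variable genes held 24.3% and 21.1% of their variance, and the groups overlapped on both. No pair of libraries within a group differed by as little as sampling noise would allow, so each lamb counted as 1 replicate.

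The comparison of RES with ADL asks whether livers of the 2 groups differed at the same slaughter weight. In the authors' deposited table, 13 genes had an adjusted p under 0.05, of which 5 were higher and 8 were lower in RES. The 5 higher genes included 3 cytochrome P450 genes of drug and steroid oxidation, namely CYP3A24, CYP2C19 and LOC101110202, which is described as cytochrome P450 3A24-like. The other higher genes were CDC37L1, a relative of an Hsp90 co-chaperone, and LOC105605968, a pseudogene of the heat-shock protein gene DNAJA1. The 8 lower genes included 3 plasma proteins secreted by hepatocytes: transferrin (TF), which carries iron, apolipoprotein H (APOH) and prothrombin (F2). The others were the protease inhibitor cystatin C (CST3), the tartrate-resistant acid phosphatase ACP5, the mitochondrially encoded complex I subunit ND3, the ribosomal stalk protein RPLP1 and a pseudogene of RPLP1, LOC101102122.

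CYP2C19 stood at 348 ± 116 TPM in ADL and 819 ± 212 TPM in RES (mean ± SD, n = 4 each, here and for all TPM means). CYP3A24 stood at 1150 ± 168 TPM in ADL and 1956 ± 364 TPM in RES. LOC101110202 stood at 508 ± 49.4 and 749 ± 37.1 TPM. In the authors' deposited table the log2 fold change of CYP2C19, shrunken towards 0, is 0.71 ± 0.17 (SE, adjusted p = 0.0218). CYP3A24 has 0.55 ± 0.14 (adjusted p = 0.0304) in the authors' deposited table and LOC101110202 has 0.43 ± 0.08 (adjusted p = 0.000475). CDC37L1 rose from 15.3 ± 0.890 to 21.7 ± 0.839 TPM. Its log2 fold change in the authors' deposited table is 0.38 ± 0.08 (adjusted p = 0.00265). LOC105605968 rose from 36.0 ± 3.41 to 56.1 ± 7.90 TPM, with 0.47 ± 0.12 (adjusted p = 0.028) in the authors' deposited table.

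Among the lower genes, ND3 fell from 1751 ± 226 TPM in ADL to 1057 ± 189 TPM in RES. Its log2 fold change in the authors' deposited table is -0.69 ± 0.13 (adjusted p = 0.000541). ACP5 fell from 81.8 ± 4.75 to 56.2 ± 8.11 TPM, with -0.57 ± 0.11 (adjusted p = 0.000541) in the authors' deposited table. TF stood at 9775 ± 351 TPM in ADL and 7643 ± 850 TPM in RES, and CST3 at 314 ± 23.2 and 222 ± 42.4 TPM. The authors' deposited table gives TF -0.42 ± 0.10 (adjusted p = 0.0123) and CST3 -0.52 ± 0.13 (adjusted p = 0.028). In the authors' deposited table APOH has -0.36 ± 0.08 (adjusted p = 0.00907) and F2 -0.37 ± 0.09 (adjusted p = 0.0433). The authors' deposited table also gives RPLP1 -0.40 ± 0.09 (adjusted p = 0.011) and LOC101102122 -0.42 ± 0.08 (adjusted p = 0.000541). For each of the 13 genes, the 4 RES lambs all lay on the same side of the 4 ADL lambs.

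**Figure D1:**
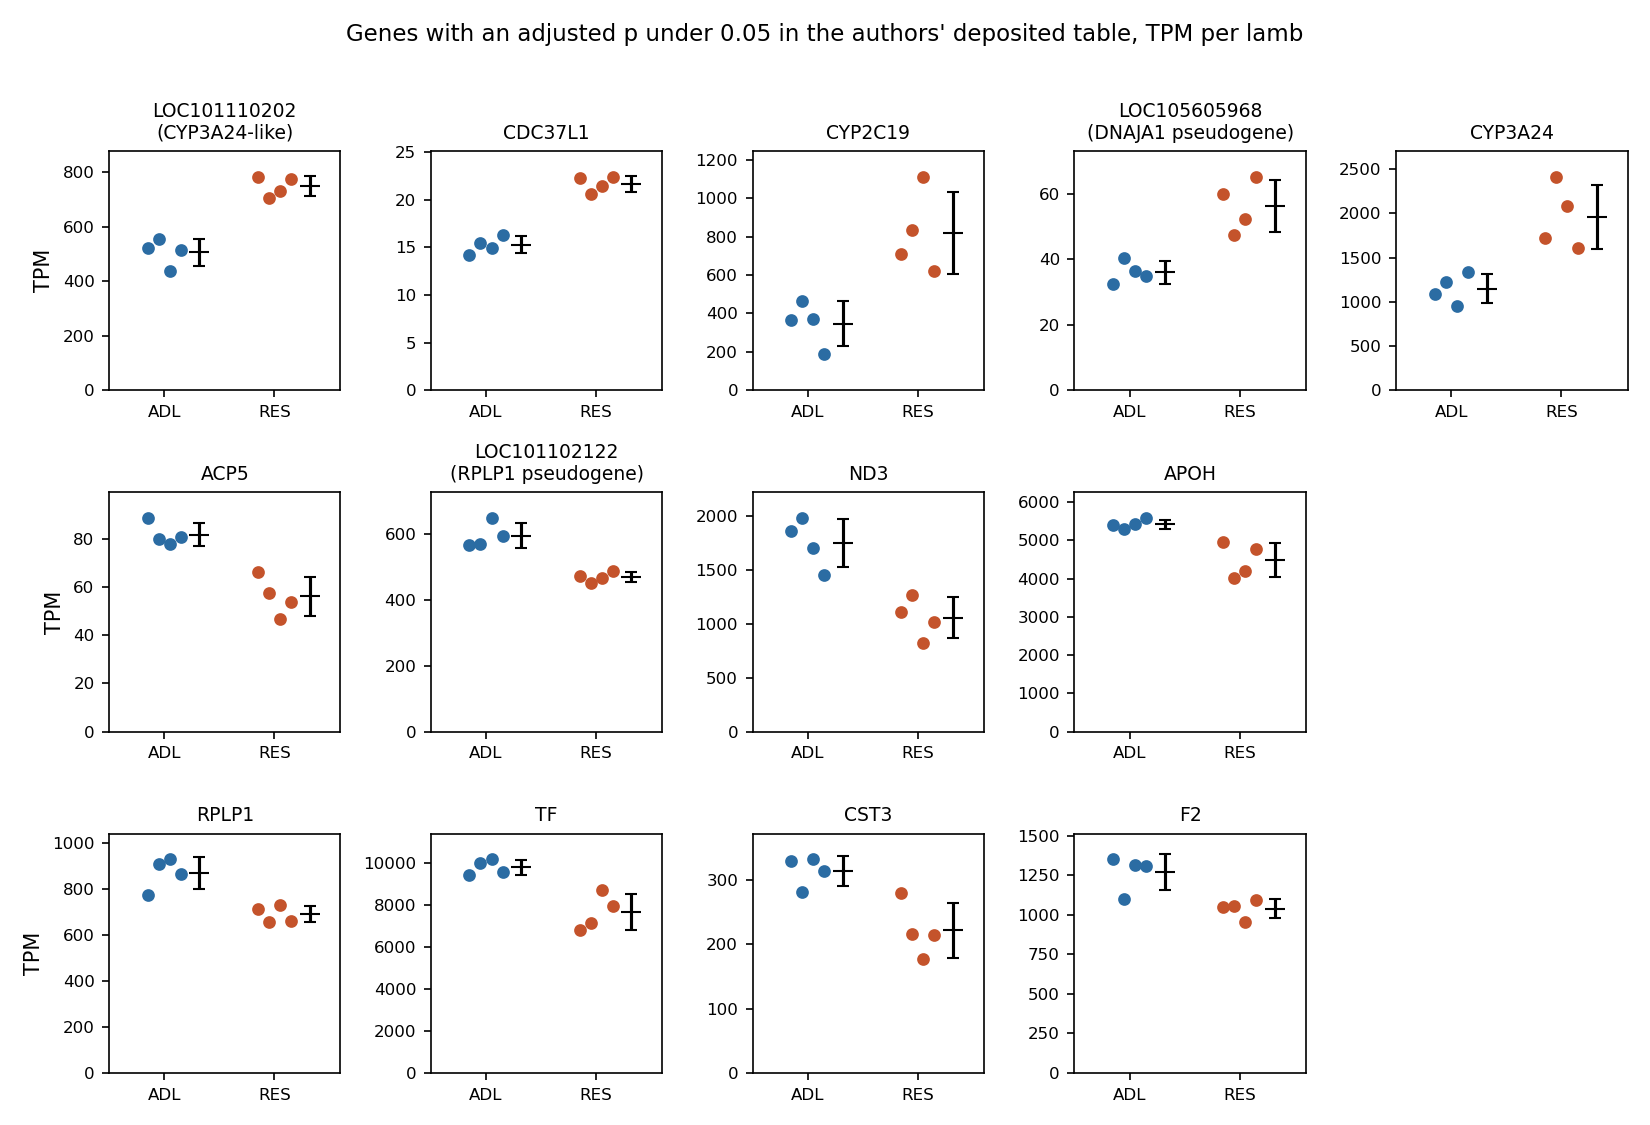
TPM of each lamb (y axis, linear from 0) in the ADL and RES groups for the 13 genes with an adjusted p under 0.05 in the authors' deposited table. Points are lambs and the bar beside each group is its mean with the SD over 4 lambs; the 5 genes of the top row are higher and the 8 below are lower in all RES lambs than in any ADL lamb.

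CYP3A24 lies on chromosome 24 from 36538476 to 36615766 in the coordinates of the authors' annotation. Its genome build is not given in the sources used here. LOC101110202 lies nearby, from 36464991 to 36524779. Reads can be shared between such paralogs, and between a gene and its pseudogenes, so the values of CYP3A24, LOC101110202, CYP2C19, LOC105605968, RPLP1 and LOC101102122 are uncertain as values of single genes. LOC105605968 is annotated on chromosome 1 from 228813851 to 228815003, and DNAJA1 itself on chromosome 2 from 37921876 to 37932306. ND3 lies on the mitochondrial genome from 9469 to 9814 and TF on chromosome 1 from 253430521 to 253512980. APOH lies on chromosome 11 from 61429202 to 61441684 and F2 on chromosome 15 from 74785348 to 74799496. CST3 is annotated on chromosome 13 from 41232932 to 41236870 and ACP5 on chromosome 5 from 13519926 to 13523538. CYP2C19 has no chromosome position in that annotation, and its gene length is only 314 bases.

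At an adjusted p under 0.1 the authors' deposited table holds 38 genes, 15 higher and 23 lower in RES. The authors' deposited table gives an adjusted p for 5627 of its genes, none with a mean normalized count below 278.3. Its p adjusted again over the 13418 tested genes that have one called 19 genes, 12 of the 13 and 7 without a deposited adjusted p. F2 was the 1 gene lost (0.0671), and KLHL13 had the smallest adjusted p of the 19 (1.5e-05). Of its 22130 genes with a p, 1147 lie under an unadjusted 0.05, where 1106 would by chance if p were spread evenly. The median p was 0.568, so p leaned to high values and 1106 is only a rough mark. These genes include ones below a mean of 1 TPM, which the limma fit left out. All 38 had the same direction in the limma fit to the TPM values, 37 had an unadjusted p under 0.05 there, and 31 had groups that did not overlap. Both fits rest on the same reads, and the 38 were picked by a small p, so these counts are not separate evidence.

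The limma fit to the TPM values called 0 of the 13437 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.395. At an unadjusted p under 0.05 it had 1594 genes, 1393 higher and 201 lower in RES, where chance would give 672. The higher count was 780 without ADL lamb 3, and the lower count was 319 without RES lamb 1. The split also followed the scaling. The median gene lay 0.09 log2 units higher in RES in the deposited TPM values. Division by size factors moved that median to 0.01 and left 457 higher and 571 lower genes, 0 of them past an adjusted p of 0.05. Limma's voom on the reads recovered from the table called 0 genes too, with 1052 at an unadjusted p under 0.05. In the deposited TPM values, which hold the shift of the median gene, the groups did not overlap for 993 genes. That is 7.39% of those tested, against the 2.86% that chance gives on average. The share after scaling was not computed.

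On the higher side, none of the genes closest to the limma threshold was past it. After CDC37L1, LOC101110202 and LOC105605968 came the sulfotransferase 1C1 gene LOC101115778, at 1.45 ± 0.541 TPM in ADL and 4.23 ± 1.27 in RES (log2 difference 1.09 ± 0.21, SE). Next were a tubulin beta chain gene, LOC101108730 (5.47 ± 0.750 against 9.01 ± 1.05 TPM), and the thiopurine methyltransferase TPMT (27.0 ± 1.74 against 36.7 ± 2.25 TPM). SLC13A5, the citrate transporter of the plasma membrane, stood at 4.44 ± 1.67 TPM in ADL and 11.1 ± 2.16 TPM in RES (1.20 ± 0.24). RBM18, CYP3A24 and CCDC117 completed the 10. Each of these 10 genes had the limma adjusted p of 0.395 and was higher in all 4 RES lambs than in any ADL lamb.

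On the lower side, none of the 10 genes with the smallest p was past the threshold either. The chemokine receptor CXCR4 stood at 3.55 ± 0.691 TPM in ADL and 1.63 ± 0.267 TPM in RES (log2 difference -0.78 ± 0.14, SE). The high-affinity IgG receptor FCGR1A stood at 2.10 ± 0.560 and 0.892 ± 0.299 TPM (-0.71 ± 0.17). Folate receptor beta, LOC101121452, stood at 14.0 ± 1.08 and 9.64 ± 0.957 TPM (-0.49 ± 0.10). ACP5, ND3 and LOC101102122 were again among the 10. The others were KLHL13 (-0.58 ± 0.11), PHF7 (-0.58 ± 0.13), the uncharacterized LOC105604962 (-0.54 ± 0.12) and RGS6. RGS6, a regulator of G-protein signalling, stood at 4.29 ± 2.54 TPM in ADL and 0.295 ± 0.283 TPM in RES. Its groups overlapped because 1 ADL lamb lay at 0.628 TPM. All 10 had a limma adjusted p of 0.395. Without ADL lamb 1, RGS6 alone passed, at -2.35 ± 0.19 and an adjusted p of 0.0202. On the log2(TPM + 1) scale the differences of such low genes are understated.

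Gene lists written for liver metabolism, hormone axes, stress, immunity and the cell types of the liver were then compared with all other genes by camera. The genes of cytosolic ribosomal proteins, the mitochondrially encoded genes and the apolipoproteins stood lower in RES relative to other genes, and the list of immediate-early and heat-shock genes stood higher. In all, 12 of the 42 lists with at least 5 measured members passed an adjusted p of 0.05 with camera's preset correlation, 11 lower and 1 higher. None of the 12 passed with an estimated correlation between genes, where the smallest adjusted p was 0.228. For apolipoproteins and hepatocyte markers the estimates, -0.00387 and 0.0069, lay below the preset 0.01. Their unadjusted camera p still rose, from 9.51e-05 to 0.00544 and from 0.00362 to 0.0247. A stronger correlation was thus not the reason in these 2 lists. For the rest of the 12 the estimate lay between 0.0408 and 0.666. No member of any list passed when adjusted over all genes, and 16 memberships passed when adjusted over the list alone.

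Of the 76 genes of cytosolic ribosomal proteins, 57 were lower in RES, or 70 after size-factor scaling. The median log2 difference was -0.08, or -0.18 scaled (camera adjusted p = 7.15e-13, adjusted p = 0.674 with an estimated correlation). RPLP1 stood at 871 ± 69.6 TPM in ADL and 692 ± 36.4 TPM in RES, and RPS12 at 24.8 ± 3.28 and 19 ± 0.478 TPM. In this list 0 members passed when adjusted over the list alone. All 13 mitochondrially encoded genes, subunits of the respiratory chain and ATP synthase, were lower. Their median was -0.18 (camera adjusted p = 2.96e-06, adjusted p = 0.674 with an estimated correlation). ND3 was the 1 member past the threshold when adjusted over the list alone. Of 19 apolipoprotein and lipoprotein assembly genes 13 were lower, with a median of -0.18 (camera adjusted p = 8.43e-04, adjusted p = 0.228 with an estimated correlation). Here too 0 passed when adjusted over the list alone. They include APOM, which carries sphingosine 1-phosphate on lipoproteins, at 121 ± 10.6 TPM in ADL and 96.1 ± 9.45 TPM in RES. APOH stood at 5424 ± 121 and 4484 ± 453 TPM.

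Lists of hepatocyte metabolism that passed with the preset correlation had small differences, and none of their members passed when adjusted over the list alone. Propionate and branched-chain amino acid breakdown had a median of -0.02 over 24 genes (camera adjusted p = 8.43e-04, adjusted p = 0.674 with an estimated correlation). ACSM3 stood at 755 ± 73.0 and 604 ± 50.1 TPM and the propionyl-CoA carboxylase subunit PCCB at 224 ± 20.8 and 188 ± 23 TPM in ADL and RES. Fatty acid oxidation and ketogenesis had a median of -0.06 over 31 genes (camera adjusted p = 0.00132, adjusted p = 0.735 with an estimated correlation). The acyl-CoA synthetase ACSL1 went the other way, at 129 ± 23.6 and 180 ± 38.5 TPM, and ECI1 stood at 198 ± 21.1 and 172 ± 22.4 TPM. Amino acid breakdown and the urea cycle had a median of -0.03 over 39 genes (camera adjusted p = 0.00501, adjusted p = 0.735 with an estimated correlation). GNMT stood at 18.6 ± 1.04 and 23.3 ± 1.83 TPM and AGXT at 61.1 ± 7.79 and 49.6 ± 1.42 TPM. The 56 nuclear genes of oxidative phosphorylation split evenly, 28 higher and 28 lower. Their median was -9.05e-04 and their mean 0.01, on opposite sides of 0 (camera adjusted p = 0.011 on the lower side, adjusted p = 0.779 with an estimated correlation). Scaled, 47 were lower and the median was -0.10. NDUFA13, at 139 ± 7.15 and 121 ± 9.33 TPM, and NDUFA1, at 6.61 ± 0.927 and 8.89 ± 1.38 TPM, moved in opposite directions. Without RES lamb 4 the calls of these 4 lists ended, with camera adjusted p of 0.116, 0.0616, 0.248 and 0.513 in that order. Without RES lamb 3 the calls of fatty acid oxidation (0.055), amino acid breakdown (0.055) and oxidative phosphorylation (0.105) ended, and without ADL lamb 1 that of oxidative phosphorylation (0.0576).

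The 23 measured immediate-early and heat-shock genes had a median log2 difference of 0.33, or 0.24 scaled, with 20 of them higher in RES (camera adjusted p = 0.00633, adjusted p = 0.735 with an estimated correlation). When adjusted over the list alone, 7 members passed. Among them were the chaperone genes DNAJA1 (13.7 ± 1.93 TPM in ADL, 20.7 ± 2.23 in RES) and HSPH1 (9.44 ± 1.87 and 17.7 ± 6.41 TPM). The transcription factor genes ATF3 (2.03 ± 0.472 and 3.48 ± 0.554 TPM) and JUN (6.37 ± 0.965 and 10.4 ± 2.60 TPM) were others. After size-factor scaling 1 member passed, as with no filter on low values, with voom and with the length trend removed. The count was 0 with the lamb number as a block, 0 without ADL lamb 1, RES lamb 1 or RES lamb 4, 1 without ADL lamb 4 and 3 without ADL lamb 3. The list's own call ended without RES lamb 1 (camera adjusted p = 0.164).

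**Figure D2:**
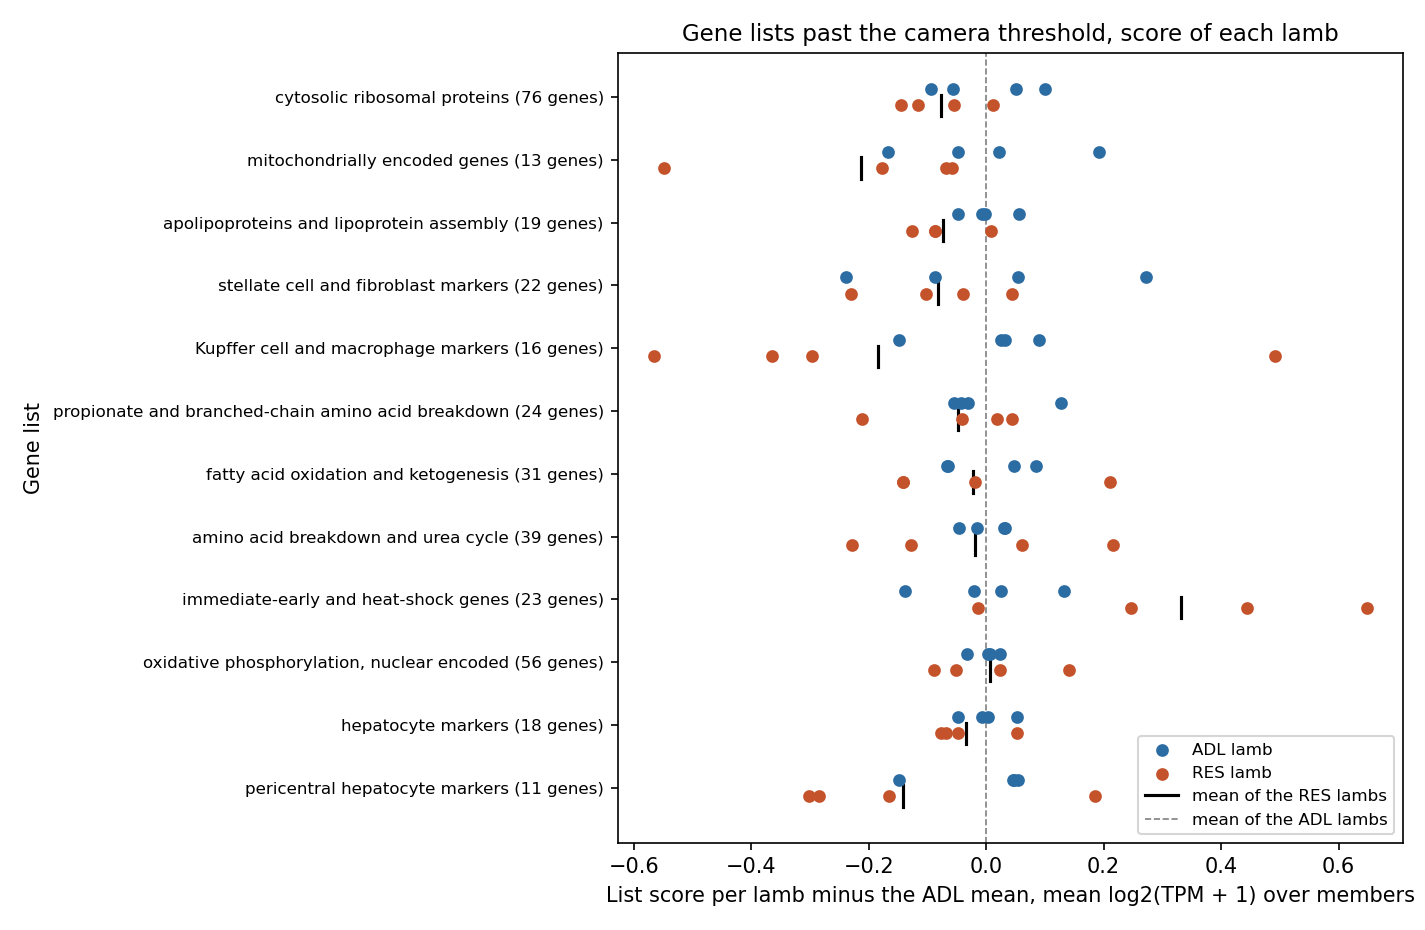
Score of each lamb, the mean log2(TPM + 1) over the members of a list minus the mean of the ADL lambs (x axis), for the 12 lists past the camera threshold (y axis). Blue points are ADL lambs, orange points RES lambs and black bars the RES means; the points of the groups overlap in each of the 12 lists, which camera compared with the other genes and not with the spread of these scores.

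Genes of bile acid and drug handling were among the few that passed when adjusted over their own list, although those lists did not pass as a whole. In the list of bile acid synthesis and transport (16 genes, camera adjusted p = 0.528), 3 members passed. They were the sterol export pair ABCG5 (5.40 ± 1.39 TPM in ADL, 9.51 ± 1.49 in RES) and ABCG8 (11.5 ± 3.08 and 19.6 ± 3.65 TPM), and the bile acid responsive nuclear receptor NR0B2 (7.15 ± 2.27 and 14.4 ± 4.20 TPM). The count was 0 after size-factor scaling, with voom or with the length trend removed, 0 without ADL lamb 3 or 4 or RES lamb 2 or 3, 1 without RES lamb 4 and 2 without ADL lamb 1 or 2. ABCG5 and ABCG8 adjoin on chromosome 3, from 80200805 to 80232162 and from 80180144 to 80200774. Of 26 phase I genes (camera adjusted p = 0.685), CYP3A24, CYP2C19 and the lipid droplet enzyme HSD17B13 (502 ± 62.1 and 689 ± 60.9 TPM) passed, 2 after scaling, and 0 without RES lamb 2 or RES lamb 3. Leaving out ADL lamb 1, 2 or 4 or RES lamb 4 left 2. HSD17B13 is also a member of the periportal hepatocyte list (12 genes, camera adjusted p = 0.741). TPMT was the 1 of 26 phase II genes (camera adjusted p = 0.528) to pass. The count was 0 after scaling, with voom, with the length trend removed or with the lamb number as a block, 0 without ADL lamb 2 or 4 or RES lamb 2 or 3, and 2 without RES lamb 1.

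Lists that did not pass with the preset correlation and unscaled values held some of the larger medians. Over 25 genes of fatty acid and triglyceride synthesis the median log2 difference was 0.34, with 23 genes higher in RES (camera adjusted p = 0.19, or 0.0384 after size-factor scaling; unscaled, adjusted p = 0.947 with an estimated correlation). The elongase ELOVL6 stood at 19 ± 6.56 TPM in ADL and 28.5 ± 2.84 in RES and the acyltransferase GPAM at 32.9 ± 3.57 and 43.4 ± 7.36 TPM. Over 27 genes of endoplasmic reticulum folding and stress it was 0.24, with 24 higher (camera adjusted p = 0.0732, or 0.0164 scaled; unscaled, adjusted p = 0.947 with an estimated correlation). ATF3 and the stress sensor ATF6 had the smallest p of this list, and ATF6 stood at 22.9 ± 1.52 and 28.2 ± 2.09 TPM. The 21 acute phase genes had a median of 0.23 and a mean of 0.70 (camera adjusted p = 0.302). Their score was 8.23, 8.89, 8.47 and 8.86 in ADL lambs 1 to 4 and 9.29, 9.80, 9.08 and 9.10 in RES lambs 1 to 4. All RES lambs thus lay above all ADL lambs (exact permutation p = 0.0286, unadjusted, the smallest it can give). The unscaled scores of bile acid synthesis and transport and of apoptosis and p53 response separated likewise. After size-factor scaling the permutation p was 0.0286 for acute phase, 0.0571 for bile acid and 0.143 for apoptosis genes. These 3 lists lay outside the family of score tests. They were picked from 45 lists for reaching that floor unscaled, which each list does by chance with a share of 0.0286. Serum amyloid A, LOC101120204, ranged from 36.6 to 412 TPM over the ADL lambs and from 351 to 22407 TPM over the RES lambs. C-reactive protein, CRP, stood at 1956 ± 322 and 2707 ± 401 TPM. Antioxidant defence and NRF2 targets had a camera adjusted p of 0.985. The thioredoxin reductase TXNRD1 stood at 13 ± 1.10 and 18.3 ± 2.43 TPM and NFE2L2 at 13.2 ± 0.347 and 17.3 ± 2.58 TPM. None of the members named in these lists passed when adjusted over that list alone.

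**Figure D3:**
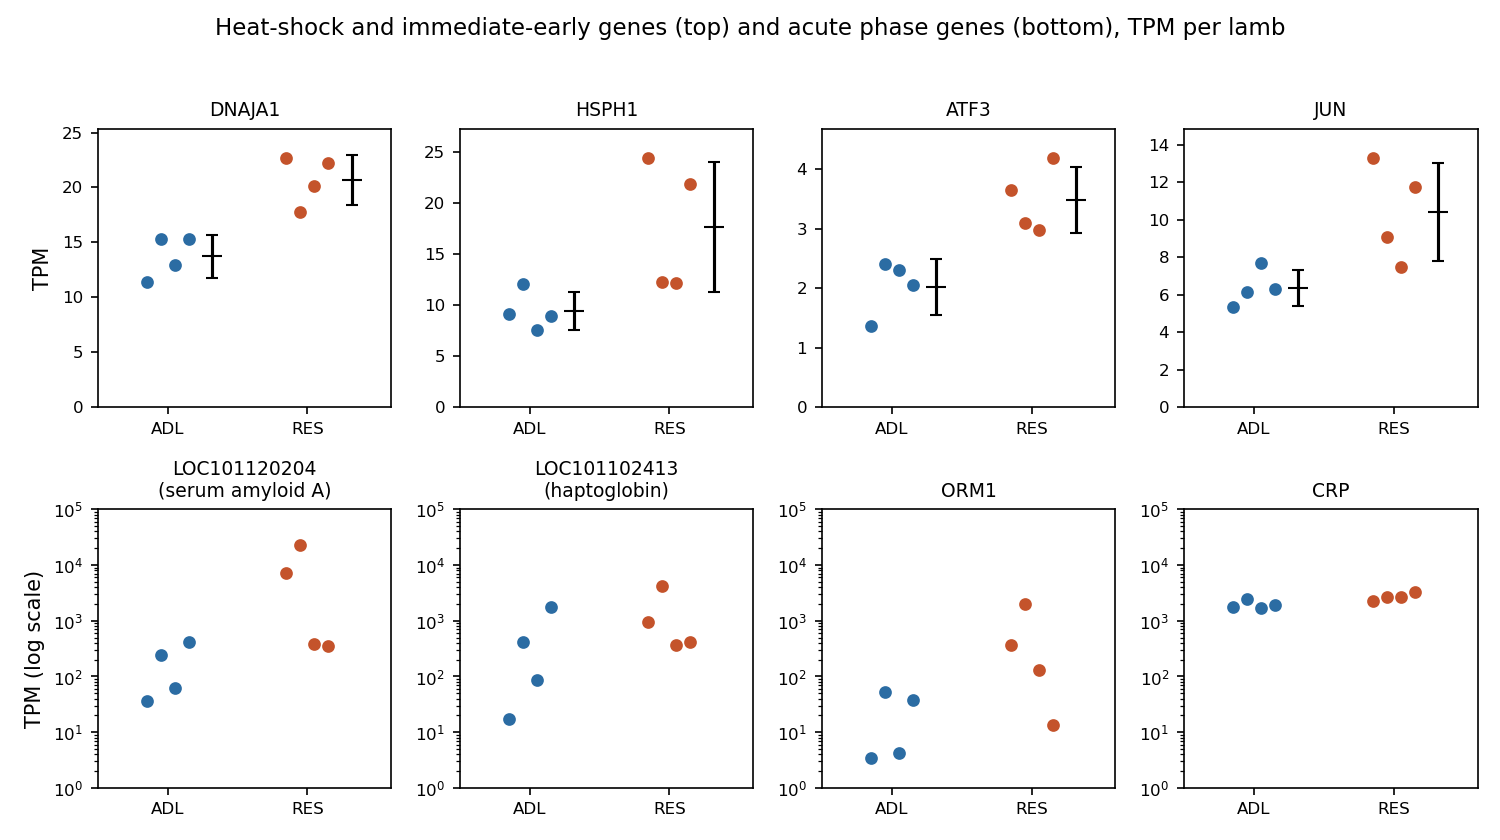
TPM of each lamb (points) in the ADL and RES groups for 4 members of the immediate-early and heat-shock list (top, linear axes from 0, with mean and SD over 4 lambs) and for 4 acute phase genes (bottom, log axes). Serum amyloid A spans 36.6 to 22407 TPM over the 8 lambs, while CRP stays between 1708 and 3234 TPM.

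Markers of the cells other than hepatocytes that a piece of liver holds were followed for the same comparison. The 16 markers of Kupffer cells and macrophages had a median of -0.14, with 12 lower in RES (camera adjusted p = 8.43e-04, adjusted p = 0.735 with an estimated correlation). TYROBP, a signalling adaptor of myeloid cells, stood at 23.4 ± 3.27 TPM in ADL and 16.2 ± 4.79 TPM in RES, and the mannose receptor MRC1 went the other way, at 36.4 ± 3.01 and 42.4 ± 1.73 TPM. The list's score lay between 5.64 and 5.88 over the ADL lambs and at 6.28, 5.42, 5.49 and 5.22 in RES lambs 1 to 4. Without RES lamb 4 its camera adjusted p was 0.165. The 22 markers of stellate cells and fibroblasts had a median of -0.13 (camera adjusted p = 8.43e-04, adjusted p = 0.735 with an estimated correlation). That call ended without ADL lamb 3 (0.139) and without RES lamb 1 (0.069). Decorin, DCN, stood at 53.9 ± 8.47 and 46.5 ± 2.62 TPM and COL6A3 at 2.15 ± 0.857 and 1.42 ± 0.423 TPM. The 18 hepatocyte markers had a median of -0.06 (camera adjusted p = 0.0138, adjusted p = 0.519 with an estimated correlation). Without ADL lamb 1 it was 0.0824. TF was lower, and arginase, ARG1, stood at 226 ± 49.2 and 314 ± 81.3 TPM. The 11 pericentral hepatocyte markers had a median of -0.14 (camera adjusted p = 0.0233, adjusted p = 0.674 with an estimated correlation). NOTUM stood at 46.3 ± 9.97 and 37.4 ± 7.51 TPM and AXIN2 at 1.86 ± 0.411 and 2.41 ± 0.546 TPM. That call ended after size-factor scaling (0.0947) and without ADL lamb 3 (0.0759), ADL lamb 4 (0.107), RES lamb 1 (0.0829) or RES lamb 4 (0.0948). No member of these 4 lists passed when adjusted over the list alone.

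Markers of endothelium, bile ducts, T and natural killer cells, and neutrophils and monocytes had camera adjusted p between 0.734 and 0.965. Each lamb's score was also compared between the groups by an exact two-sided permutation test over the 70 assignments of the labels, whose smallest possible p is 0.0286. In the family of 20 lists so tested, 0 passed after adjustment; the smallest adjusted p by this permutation test was 0.57. A pass would have needed at least 12 of the 20 lists at the smallest possible p, so this count says little about any list.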

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

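The tests of the splits for genes past an adjusted p and for genes with an unadjusted p in the deposited TPM values, those of the heat-shock genes by splits, by parts of their list and for a handling response, the spread set against the trends of the ribosomal protein genes, and the test of the smaller family of tests were chosen only after the result was seen.

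In 9 of 178 groups of 4 values tested, 1 lamb stood far from the other 3 of its group, and chance alone would give 8.9. In ADL, APOM was 136.7 TPM in lamb 1 against at most 116.9 in the others, GNMT 20.1 TPM in lamb 2 against at most 18.2, and citrate synthase, CS, 18.17 TPM in lamb 4 against at most 15.34. ADL lamb 1 also had the highest score for propionate and branched-chain amino acid breakdown, 6.63, and the lowest for pericentral hepatocyte markers, 5.603. In RES, ACSM3 was 679 TPM in lamb 3 against at most 586 in the others, PCCB 154 TPM in lamb 4 against at least 198, NFE2L2 21.2 TPM in lamb 4 against at most 16.4, and NOTUM 26.2 TPM in lamb 1 against at least 40.3.

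Ribosomal protein genes stood lower in RES, by a median of -0.173 ± 0.0644 log2 units relative to all genes (SE over lambs), a call that ended with an estimated correlation (adjusted p = 0.674). Trends on gene length or expression level cannot be told apart from an effect of the group: removing them left -0.109 ± 0.0462 and -0.125 ± 0.0395, neither past -0.0865, the midpoint between 0 and -0.173, by more than its SE (camera adjusted p = 5.95e-07 and 1.33e-07, or 0.769 and 0.941 with an estimated correlation). Chance in the grouping of the lambs cannot be excluded: 2 of the 35 splits of the 8 lambs, the real one included, gave a mean difference as large, with 0.168 for the real split and 0.182 for the highest other. The same holds for the count of lists, since 18 of the 35 splits gave at least the 12 lists of the real one and the highest other gave 19. A response to feeding that differed between the groups stays open and untested apart from these splits.

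The list of immediate-early and heat-shock genes stood higher in RES, and so did 8 other loci described as copies of DNAJA1. For the whole list of 23 genes, 6 of the 35 splits gave a difference as large (real 0.239, highest other 0.370). Chance cannot be excluded for the list. In the score of its 10 heat-shock members, a part looked at only after the result was seen, all 4 RES lambs lay above every ADL lamb. Without DNAJA1 the list had an unadjusted camera p of 0.00474 at the preset correlation and 0.32 with an estimated one. At the preset correlation the call thus did not hang on that gene. Leaving out 1 of 23 members moved the relative mean only from 0.239 to 0.229, so this test says little about shared reads. The whole list's call itself ended with an estimated correlation (adjusted p = 0.735) and without RES lamb 1 (0.164). The copies themselves lay within 1.63 standard errors of DNAJA1, which is consistent with reads shared between them. A handling response at sampling cannot be told apart from an effect of the group: the 13 immediate-early members had a mean difference of 0.22 ± 0.18 (SE; exact permutation p = 0.371), and the 10 heat-shock members had 0.48 ± 0.17 (exact permutation p = 0.0286, the smallest it can give), with ranges that overlap. A response to feeding that differed between the groups stays open and untested.

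The authors' table called 13 genes where limma called 0. Adjusting limma's p over the 5626 genes tested here that have a deposited adjusted p called 0 of the 13, which argues against the smaller family of tests as the cause. The 13 genes had a median ratio of 0.676 between their own SD and the SD that limma's trend expects at their level, against 1.04 over all genes. Genes picked by a small p tend to a low SD whatever the cause, so this ratio decides nothing. CDC37L1 had 0.481 ± 0.076 in limma (SE, p = 0.000135) and 0.381 ± 0.081 in the authors' table (SE, Wald p = 2.35e-06). Its limma difference was larger and its SE smaller, yet its p was larger. For this gene the gap in p thus lies in how each test turns those values into a p. Limma read them against a t distribution with 6 residual and 3.11 prior degrees of freedom, the Wald test against a normal distribution. LOC105605968 was alike, at 0.621 ± 0.116 in limma (SE, p = 0.000455) and 0.468 ± 0.116 in the authors' table (SE, Wald p = 5.47e-05). APOH was not, with -0.280 ± 0.107 in limma and -0.359 ± 0.081 in the authors' table, so there the values differed too. How much of the gap over all 13 genes lies in the 2 distributions was not computed and stays open.

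On chance, the count of 0 limma genes decides nothing, since all 35 splits must reach it (highest other 2). At an unadjusted p under 0.05, chance cannot be excluded after size-factor scaling, where 5 of 35 splits reached the 1028 genes of the real one (highest other 1283). In the deposited values, which hold the shift of the median gene, the real split was the 1 of 35 to reach its 1594 genes (highest other 1291). That is the smallest share that 35 splits can give, for 1 of several counts, in a test chosen after the result was seen. It therefore does not exclude chance for that count. The shift of the median gene was also largest in the real split (0.0947, highest other 0.0759). Without ADL lamb 3 the 1393 higher genes fell to 780.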

How the results depend on the processing

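The alternatives with voom, with the deposited family of tests, with the length trend removed and with the deposited p adjusted again were chosen after seeing the data; the others were planned. The limma count of 0 genes became 1 with no filter on low values, 0 to 1 when single lambs were left out, and 13 by the authors' deposited adjusted p. The limma count was 0 under the other alternatives. The gene called without a filter was LOC101120736, a ribosomal protein pseudogene at 0 TPM in all ADL lambs and 0.27 to 0.292 TPM in RES. Its call (0.36 ± 0.03, SE) rests on nearly equal values at the floor, whose tiny spread makes a small p. The authors' 13 calls became 38 at an adjusted p under 0.1, a looser threshold by construction, and 19, with 12 of the 13 among them, when the deposited p was adjusted again over tested genes. The 12 lists became 0 with an estimated correlation and 0 with fry, which tests a list against 0 on its own spread and not against other genes. Fry was run on unscaled values, where the median gene lay 0.0947 higher in RES. Nuclear oxidative phosphorylation had a mean of 0.00601 there and so lay on the higher side in fry (adjusted p = 0.958), though below the median gene. Single lambs left out gave 8 to 14 lists, and scaling or voom 13. With no filter the lists of amino acid breakdown (0.0744), nuclear oxidative phosphorylation (0.133), hepatocyte (0.208) and pericentral markers (0.0928) lost their calls. Removal of the length trend ended those of nuclear oxidative phosphorylation (0.153) and pericentral markers (0.116), and voom (0.106) and scaling (0.0947) ended that of pericentral markers. Ribosomal proteins, mitochondrially encoded genes and apolipoproteins kept theirs under all 14 alternatives that kept the preset correlation. Over 14 alternatives, 0 of 58 genes named in the comparison changed direction. The genes were named for a small p in these same lambs, which each alternative used again. That count was therefore nearly fixed in advance and is not separate evidence. No pairing of the lambs by number was assumed. Deviations of lambs with the same number correlated at 0.153, -0.12, 0.0545 and 0.0577, and 3 of the 4 numbers had their best partner in the same number. These values do not settle whether the numbers pair the animals. With the number as a block there were 0 genes and 14 lists. Depth was similar in all lambs, and limits genes with few reads most.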

Other observations

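The genes of this part were chosen after their values were seen. Serum amyloid A, LOC101120204, an acute phase protein made by the liver in inflammation, stood at 7146 TPM in RES lamb 1 and 22407 TPM in RES lamb 2, against 389 and 351 TPM in RES lambs 3 and 4 and 36.6 to 412 TPM in the ADL lambs. The second serum amyloid A gene, LOC105601867, stood at 3674 and 11128 TPM in RES lambs 1 and 2 and at most at 1541 TPM in the others. ORM1, another acute phase protein, stood at 361 and 2006 TPM in RES lambs 1 and 2, 133 TPM in RES lamb 3 and at most 52.3 TPM in the others, and haptoglobin, LOC101102413, at 4179 TPM in RES lamb 2 and 1745 TPM in ADL lamb 4. Interferon-induced genes peaked in another animal, RES lamb 3, with HERC6 at 80.6 TPM against at most 28.6 TPM in the other 7 lambs and IFIT1, LOC101102194, at 89.0 TPM against at most 31.0 TPM.

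RES lamb 4 stood apart in 2 imprinted genes that are expressed from the paternal copy, PEG3 at 161 TPM against at most 20.8 TPM in the other 7 lambs and PEG10 at 95.4 TPM against at most 25.7 TPM. Metallothionein genes, which bind zinc and copper, varied within both groups: LOC101117691 ranged from 3.77 to 917 TPM over the ADL lambs and from 11.6 to 882 TPM over the RES lambs, and LOC101117955 from 2.19 to 766 TPM and from 10.6 to 248 TPM. The mitochondrial gene ATP8 stood at 13291 TPM in ADL lamb 4 and 14101 TPM in RES lamb 4 and between 3490.4 and 5743 TPM in the other 6 lambs, while the adjoining ATP6 lay between 4090.3 and 6746 TPM in all 8. PDK4, a kinase that restrains glucose oxidation, stood at 303 TPM in RES lamb 1 and at most at 96.7 TPM in the others.

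Longer genes tended to stand higher in RES. From the shortest to the longest of 5 equal groups of genes by length, the median log2 difference rose from 0.04 to 0.13 in the deposited values. After scaling it rose from -0.05 to 0.05. The slope of a lamb's deviations on log2 length was -0.0105 ± 0.0107 in ADL and 0.0105 ± 0.0236 in RES (SD; exact permutation p = 0.114), a difference that did not pass the threshold. Without RES lamb 4 the difference in slope fell from 0.021 to 0.0105 and the median of the longest genes to 0.10, and without RES lamb 1 the median of the shortest fell to 0.0207.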
